A study of Mus musculus with 4 samples.

How the data were processed

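The series holds droplet RNA sequencing of mouse intestinal organoids in 4 libraries, 2 control and 2 with Cbl and Cblb deleted. Organoids were started from crypts of 2 mice, and the deletion was switched on with 4-hydroxytamoxifen at 400 nM for 3 days, per the labels' protocols. For each library the deposited file is a matrix of whole-number UMI counts, 1 count per distinct RNA molecule, for each gene and cell barcode. The counts were made with Cell Ranger 3.0.1 against mm10 per the submitters' processing notes, and software version 3.0.0 is named per the file headers. The deposited barcodes had already been restricted to called cells. They numbered 5602, against 7000 cells loaded per library and a mean recovery of 1200 per the labels' protocols. The features are 31040 Ensembl genes with symbols, of which 30921 match GENCODE M21 (GRCm38) by identifier and 30455 by symbol as well. Symbols held by several identifiers (36 of them) were kept apart. The strand setting and annotation release of the counting are not stated, so overlapping genes, and near-identical copies such as the Defa genes, are uncertain. No mitochondrially encoded gene is among the features, so the planned limit of 20% mitochondrial UMIs removed nothing, and mitochondrially encoded genes were not analysed here.

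Barcodes with under 500 genes were left out (173 of 5602). Likely doublets were scored with Scrublet as written in scanpy. Its automatic threshold marked only 19 barcodes (0.34%) and was not used. As fixed in the design, the highest scores were removed at 0.8% per 1000 barcodes in each library, which took out 70 barcodes (1.25%). The 5359 retained cells were scaled to 10000 counts, log-transformed, reduced to 2000 variable genes ranked within libraries and 30 principal components (values limited to 10), and joined into a graph of 15 neighbours with seed 1. Leiden clustering at resolution 1 gave 15 clusters. A cluster was named from fixed marker lists of 13 cell types when its score was at least 0.5 and at least 3 markers were detected. It stayed unnamed when its top 10 genes held more markers of another type than of its own, or when they held none of its own and its median UMI count was below 0.333 of its libraries'. These naming limits were set after the data were examined.

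UMI counts were summed over the cells of each library, for all cells and for each named class, so that the library is the unit (n = 2 per group). Genes were tested two-sided with the edgeR quasi-likelihood test (TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05), with the group as the only term as the design fixed. A class was to be tested with at least 20 cells in every library. The stem-like class had 16 cells in control 2, so its planned test could not be run and a minimum of 10 cells was used for it, chosen after the data were examined. The difference in effect between stem-like and enterocyte-like cells was fitted as an interaction with the library as a block. Shares of cells were compared with a two-sided exact permutation test, for which 2 against 2 libraries give a smallest possible p of 0.333, and each share has an exact Clopper-Pearson 95% interval. Intervals cover counting error only. The design, the gene lists, the marker lists, the alternatives and the rule for naming genes were written before the data were examined, apart from the exceptions named here and in the closing section.

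The numbers 1 and 2 pair the samples. The labels give 2 mice as the source, and the deposited files carry the same mouse tag for the control and the knockout library of each number. Across genes, deviations from the group means of same-numbered libraries correlated at 0.665 in all cells (13250 genes), 0.144 in stem-like (9598), 0.562 in cycling-like (11466), 0.514 in enterocyte-like (9015), 0.475 in goblet-like (10370) and 0.224 in Paneth-like cells (6652). The fit with the replicate number as a block, planned as an alternative, is therefore given beside the counts of genes, and beside tests of lists where it changes a call. It leaves 1 residual degree of freedom against 2 without the block, and none once a library is left out. The edgeR fit therefore takes much of the spread of a gene from the other genes of the same set of cells. Adjusted p and counts of calls with the block are thus not comparable between classes. As a check against a library deposited under 2 names, counts of the controls gave a chi-square of 87.0 per degree of freedom (13939 genes) and those of the knockouts 60.7 (14224 genes).

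Gene lists were tested with limma's camera (preset correlation 0.01, two-sided, at least 3 tested members, log2 CPM with a prior count of 2), with camera using an estimated correlation, and with fry. The 31 lists were crypt base stem cell, Wnt target, DNA replication (S phase), mitosis (G2/M), enterocyte, goblet cell, Paneth cell, enteroendocrine cell, tuft cell, Notch response, secretory fate, EGFR family and ligands, ERK feedback, immediate early and dissociation, FOXO target, glycolysis and hypoxia, sterol synthesis, amino acid response (ATF4), unfolded protein response, YAP and fetal-like, p53 target, interferon response, MHC class II, antimicrobial and NF-kB, xenobiotic metabolism, ribosomal protein, mitochondrially encoded, and 4 lists of other cell types (immune, mesenchymal, endothelial, erythroid). Members were also counted past the threshold over all genes and adjusted over the list alone.

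The named genes are Cbl, Cblb, Cblc and 11 fixed genes, then the 10 largest rises and falls in all cells (5 in each class) among genes past the threshold, with average log2 CPM of at least 5 and the same direction in both numbers. Where none passed, the 5 smallest unadjusted p per direction were taken. Each list gives up to 4 members past the threshold over all genes or over the list alone, or else its 2 most expressed members. Numbered gene models were skipped among the top genes.

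Each test was tested on simulated counts with 200 genes changed. The counts were drawn around a mean per mouse, with the noise estimated in the fit with the block. They therefore favour the block by construction and do not test whether it suits these data. At 2-fold in all cells (13233 genes) the fit without the block recovered 0% of changed genes and the fit with the block 85.9%, with 9.9% of its calls false. DESeq2 recovered 40.3% (12113 genes). With the block, 2-fold changes were recovered at 78.1% in stem-like (9596 genes), 83.3% in cycling-like (11496), 77.3% in enterocyte-like (9031), 82.1% in goblet-like (10314) and 35.5% in Paneth-like cells (6668). Without it these shares were 37.5%, 40.9%, 0%, 16.4% and 4.8%. The interaction (10517 genes) recovered 0% at 2-fold and 33.3% at 4-fold. A planted list of 20 genes at 1.5-fold was called by camera with the preset correlation in all 8 fits, and by neither the estimated correlation nor fry. The lists were random genes drawn independently of each other. The simulation therefore cannot show how often the preset correlation gives false calls for lists whose members vary together.

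Alternatives were DESeq2 and its size factors, no filter, at least 1000 genes per barcode, doublets kept, equal cells per library, class shares held fixed at those of the controls, the replicate block, other clusterings, and leaving out each library in turn. Leaving out a library puts 1 library in an arm, which is then assumed to vary like the other arm. The block in combination with these, the block in the interaction, limma with the block, and stem-like with cycling-like cells together were added after the data were examined. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.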

Results

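RNA was measured in single cells of mouse intestinal organoids, cultures grown from crypts that hold stem, dividing and differentiated epithelial cells. Organoids from 2 mice were grown without (control) or with 4-hydroxytamoxifen, which switches on the deletion of Cbl and Cblb (knockout). Each mouse gave 1 library of each group, so every comparison rests on n = 2 libraries per group, and the numbers 1 and 2 mark the mice. Cbl and Cblb encode ubiquitin ligases known for marking activated receptor tyrosine kinases, such as EGFR, for degradation. The comparison asks what their loss does to the cell types and genes of the epithelium. Controls 1 and 2 held 1208 and 709 barcodes with 27855911 and 22139560 UMIs, and knockouts 1 and 2 held 1702 and 1983 barcodes with 28597336 and 35592468 UMIs. After filtering, 1148, 682, 1627 and 1902 cells remained, with median depths of 19595, 27610, 16093 and 17495.5 UMIs per cell, so knockout cells were less deeply covered in both numbers. Log2 fold changes are knockout minus control ± SE. For genes, the fit with the group alone is named as such, and other values and the words rose and fell refer to the edgeR fit with the replicate number as a block, since the numbers pair the samples. Camera, the test of gene lists, was run with the group alone unless the block is named, and the block is given where it changes a call.

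Summed over all cells, both targeted genes had fewer counts in the knockout library of each mouse. In CPM, UMI counts scaled to library size, Cbl (ENSMUSG00000034342, GRCm38 chromosome 9, 44142976 to 44234049) had 17.1 CPM (95% interval 15.6 to 18.7) and 20.1 CPM (18.3 to 22) in controls 1 and 2. It had 12.4 CPM (11.1 to 13.8) and 10.5 CPM (9.45 to 11.6) in knockouts 1 and 2, which is 72.7% and 52.3% of the control of the same number. Cbl fell (log2 fold change −0.74 ± 0.14, adjusted p = 0.0180), while the fit with the group alone gave −0.74 ± 0.17, adjusted p = 0.556. In cycling-like cells Cbl went from 19.5 and 22.1 CPM in controls to 12.5 and 9.80 CPM in knockouts 1 and 2. In enterocyte-like cells it had 14.0 and 15.5 against 13.0 and 12.8 CPM. Paneth-like cells had 5.13 and 6.32 against 4.30 and 5.44 CPM, and enteroendocrine-like cells 24.2 and 36.5 against 28.1 and 26.4 CPM. Intervals overlapped in these last classes, so no loss of Cbl counts is shown there. Cblb (ENSMUSG00000022637, chromosome 16, 52031225 to 52208048) had 8.50 CPM (7.44 to 9.66) and 3.96 CPM (3.17 to 4.89) in the controls and 3.40 CPM (2.75 to 4.15) and 0.464 CPM (0.265 to 0.754) in the knockouts, or 40.0% and 11.7% of control. Its fold change did not pass the threshold in either fit (−1.99 ± 0.43, adjusted p = 0.0506 with the block, −1.76 ± 0.95, adjusted p = 0.587 without), and the intervals of control 2 and knockout 1 overlapped. The related gene Cblc (ENSMUSG00000040525, chromosome 7, 19778881 to 19796809), which was not targeted, also fell (−0.43 ± 0.08, adjusted p = 0.0177), to 80.9% and 72.4% of control, against −0.44 ± 0.35, adjusted p = 0.688 in the fit with the group alone. That fall is of the sum over all cells. In enterocyte-like cells, where Cblc was highest among the 5 tested classes, it had 126 and 135 CPM in controls and 145 and 147 CPM in knockouts 1 and 2, and in cycling-like cells 32.5 and 40.2 against 28.4 and 39.1 CPM, and it passed the threshold in none of the 5 classes. The deleted exons and the position of the sequenced tags are not given, and a tag outside the deleted part checks nothing. Egfr was at 0.01 ± 0.12, adjusted p = 0.979.

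**Figure D1:**
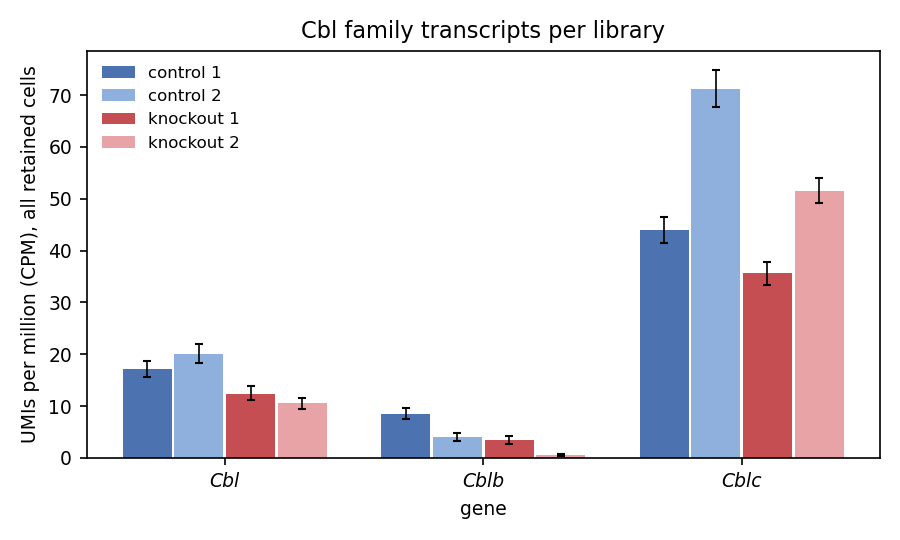
Bars give CPM of Cbl, Cblb and Cblc over all retained cells of each of the 4 libraries, with exact Poisson 95% intervals. Cblb goes from 8.50 to 3.40 CPM in number 1 and from 3.96 to 0.464 CPM in number 2.

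Fewer cells of the knockout libraries were enterocyte-like, the absorptive cells of the villus, and more were cycling-like, although with libraries aligned by ComBat the cycling-like difference of means went from 10.2 to 3.62 percentage points (from 13.5 to 1.88 in mouse 2). Enterocyte-like cells made up 13.2% (95% interval 11.3 to 15.2) and 33.3% (29.8 to 37.0) of control 1 and 2 cells, and 6.27% (5.14 to 7.56) and 11.6% (10.2 to 13.1) of knockout 1 and 2 cells. Cycling-like cells, marked by Top2a and Birc5, made up 26.5% (23.9 to 29.1) and 24.0% (20.9 to 27.4) of control and 33.4% (31.1 to 35.8) and 37.5% (35.4 to 39.8) of knockout cells. Stem-like cells, led by Olfm4, made up 12.4% (10.5 to 14.4) and 2.35% (1.35 to 3.78) of control and 17.8% (16 to 19.8) and 4.42% (3.54 to 5.44) of knockout cells. Goblet-like cells stood at 16.3% and 15.5% in the controls and 8.97% and 16.5% in the knockouts. Paneth-like cells stood at 5.23%, 4.55%, 5.10% and 6.52% in the same order, enteroendocrine-like cells at 4.53%, 1.61%, 4.18% and 4.21%, and tuft-like cells at 0.784%, 0.587%, 0.615% and 0.421%. The group means were 23.2% ± 14.2 (SD, n = 2) against 8.94% ± 3.78 for enterocyte-like, 25.3% ± 1.72 against 35.5% ± 2.90 for cycling-like and 7.36% ± 7.09 against 11.1% ± 9.48 for stem-like cells. Two-sided exact permutation p was 0.333 for the enterocyte-like and cycling-like shares, the smallest that 2 against 2 libraries allow, and 0.667 for the stem-like share, so no share can pass a threshold of 0.05. The stem-like share separated the mice more than the groups, and was higher in the knockout by 5.46 percentage points in mouse 1 and 2.07 in mouse 2. Its difference of unpaired means, 3.76 percentage points, turned to −1.25 without control 2 and to −2.94 without knockout 1.

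**Figure D2:**
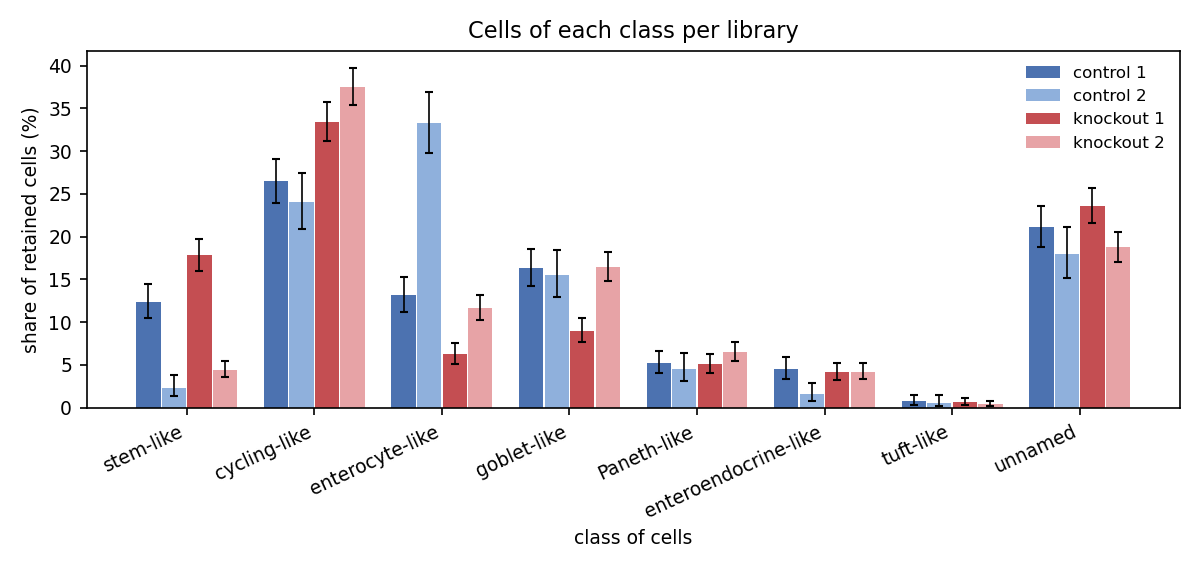
Bars give the percentage of retained cells in each named class and in unnamed clusters for each of the 4 libraries, with exact Clopper-Pearson 95% intervals. Enterocyte-like cells are at 13.2% and 33.3% in controls 1 and 2 and at 6.27% and 11.6% in knockouts 1 and 2.

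Unnamed clusters held 21.2% and 18.0% of control and 23.6% and 18.8% of knockout cells. The largest, a cluster of low depth led by Gm26917 and Lars2, held 9.41%, 5.13%, 11.6% and 8.57% in controls 1 and 2 and knockouts 1 and 2. A cluster led by Fabp6 held 7.49%, 4.69%, 6.33% and 3.21%, and a cluster of histone genes held 3.48%, 1.03%, 5.04% and 2.47%. A cluster with Clu, Ly6d and Anxa1, genes known from regenerating and fetal-like epithelium, held 0.784%, 7.19%, 0.615% and 4.52%, so most of its cells came from mouse 2. Within the cycling-like class, cluster 1 held most cells of number 1 (77.6% in control 1, 70.6% in knockout 1) and cluster 2 most cells of number 2 (59.8% and 68.3%). Within the enterocyte-like class, cluster 13 held 58.3% of control 1 cells while cluster 3 held 59.8% of knockout 1 cells and 95.2% and 95.9% of the number 2 cells. Markers of other cell types, apart from Vim, were scarce in all 4 libraries. Immune markers had 4.72, 8.65, 4.65 and 6.01 CPM and mesenchymal markers without Vim 0.95, 0.96, 0.50 and 0.52 CPM. Vim is on the fixed mesenchymal list but was left out of this sum. It stood at 883.9 CPM in the enteroendocrine-like cluster and at 3.8 CPM or less in every other cluster. Endothelial markers had 7.47, 5.51, 12.16 and 10.53 CPM, glial markers 2.45, 2.32, 2.36 and 1.25 CPM, and erythroid markers 0 UMIs, which allows up to 0.110, 0.137, 0.107 and 0.0871 CPM.

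Summed over all cells, 748 genes rose and 1213 fell in the knockout libraries. Slc25a4, the mitochondrial ADP/ATP carrier, had the largest rise among genes past the threshold with an average log2 CPM of at least 5 (log2 fold change 1.26 ± 0.16, adjusted p = 0.0145), with 34.2 and 17.8 CPM in controls 1 and 2 and 69.6 and 54.0 CPM in knockouts 1 and 2. The crypt base genes Igfbp4 (0.92 ± 0.08, adjusted p = 0.00103) and Olfm4 (0.78), the p53 targets Ccng1 (0.86) and Aen (0.84), and Cd44 (0.70), Rgcc (0.77), Srm (0.71), Siva1 (0.70) and Tipin (0.65) also rose. Ly6d had the largest fall among them (−2.18 ± 0.18, adjusted p = 0.00587), although mouse 2 set its level (24.2 and 408 CPM in controls 1 and 2 and 4.11 and 111 CPM in knockouts 1 and 2). The other named falls were in Cyp3a11 (−2.01), Slc5a4b (−1.92), Aldh1a1 (−1.81 ± 0.08, adjusted p = 2.06e-04), Enpep (−1.76), Cyp2b10 (−1.74), Spink1 (−1.68), Aoc1 (−1.66), Slc6a19 (−1.55) and Mt4 (−1.55). Of the fixed genes, Alpi, the enterocyte alkaline phosphatase, fell (−1.30 ± 0.10, adjusted p = 6.30e-04), with 31.4 and 73.4 CPM in controls 1 and 2 and 14.5 and 28.1 CPM in knockouts 1 and 2. Lgr5 was at 0.84 ± 0.33, adjusted p = 0.260, Ascl2 at −0.27 ± 0.14, adjusted p = 0.279, Smoc2 at 0.60 ± 0.17, adjusted p = 0.0890 and Mki67 at 0.24 ± 0.08, adjusted p = 0.0868. Lyz1 (−0.12), Muc2 (−0.31), Chga (0.33) and Dclk1 (−0.83) did not pass the threshold, with adjusted p of 0.660, 0.710, 0.858 and 0.0788.

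With the replicate block, 748 genes rose and 1213 fell of 13250 tested, and 1959 of these 1961 had the same direction in both mice. Among all genes tested 73.6% did. The block fit mostly calls genes whose differences agree between the mice, so this agreement follows from the selection and is no replication. The same holds in the classes below. There 56.0% (stem-like), 66.1% (cycling-like), 54.7% (enterocyte-like) and 66.7% (goblet-like) of all genes tested agreed. With the group alone, edgeR called 0 genes (1153 at unadjusted p under 0.05), and DESeq2 called 19 higher and 98 lower. The smallest unadjusted p of that fit belonged to Aen, Faim2, Ddit4l, Tmem173 and Cd44 among higher and Arg2, Ugt2b5, Slc2a5, Ugt2b36 and Treh among lower genes, all with an adjusted p of 0.556. With class shares held fixed at those of the controls, limma with the block called 53 genes higher and 38 lower, against 742 and 1185 with limma on the sums as they were. At unadjusted p under 0.05 limma had 2699 and 4272 genes. The fixed shares were shares of UMIs, had no TMM scaling and gave set weights to classes of few cells. The drop in calls therefore cannot be put on shares alone. DESeq2 with the block called 274 higher and 625 lower.

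Camera called cell cycle and crypt base lists higher, and enterocyte and xenobiotic lists lower, in all cells of the knockout. With an estimated correlation it called 0 lists (smallest adjusted p = 0.701). In the DNA replication list, 30 rose and 0 fell, against 37 and 0 adjusted over the list alone, of 42 tested (Rrm2 0.61, Mcm4 0.58, Exo1 0.64; group-alone camera adjusted p = 6.06e-15, adjusted p = 0.752 with an estimated correlation). In the mitosis list, 19 rose and 0 fell, against 28 and 0 adjusted over the list alone, of 52 (Gtse1 0.95, Psrc1 0.76; group-alone camera adjusted p = 2.03e-10, adjusted p = 0.752 with an estimated correlation). In the crypt base stem cell list, 4 rose and 0 fell, against 5 and 0 adjusted over the list alone, of 18 (Gkn3 1.36 ± 0.14, adjusted p = 0.00211, Tnfrsf19 0.83; group-alone camera adjusted p = 0.0199, adjusted p = 0.754 with an estimated correlation). In the Wnt target list, 3 rose and 0 fell, against 3 and 0 adjusted over the list alone, of 17 (Ccnd1 0.54; camera adjusted p = 0.0977, and 0.0338 with the block, adjusted p = 0.613 with an estimated correlation). In the enterocyte list, 0 rose and 11 fell, against 0 and 12 adjusted over the list alone, of 15 (Lct −2.55, Sis −1.46, Apoa1 −1.37; group-alone camera adjusted p = 1.29e-07, adjusted p = 0.709 with an estimated correlation). In the xenobiotic list, 0 rose and 12 fell, against 0 and 15 adjusted over the list alone, of 17 (Ces1f −1.42; group-alone camera adjusted p = 3.81e-07, adjusted p = 0.752 with an estimated correlation). Over the same libraries, the share of enterocyte-like cells stood at 0.477 and 0.349 of control in numbers 1 and 2.

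Camera also called stress and signalling lists in all cells, and 0 with an estimated correlation. These are sums over classes whose shares differed. With the block limma made 1927 calls, which became 91 with shares held fixed, though the scaling changed too. Reg3g, lower in the sum, rose within enterocyte-like cells (0.72). Of 20 tested p53 target genes, known for arrest and repair after DNA damage, 7 rose and 2 fell, against 11 and 3 adjusted over the list alone (Phlda3 1.95 ± 0.11, adjusted p = 2.06e-04, Eda2r 1.67, Zmat3 1.04; group-alone camera adjusted p = 0.00147, adjusted p = 0.752 with an estimated correlation). Of 15 immediate early genes, which include the heat shock genes that dissociation of tissue is known to raise, 0 rose and 13 fell, against 0 and 14 adjusted over the list alone (Hspa1b −1.12, Fosb −1.10, Dusp1 −1.07; group-alone camera adjusted p = 1.99e-08, adjusted p = 0.701 with an estimated correlation). Of 16 ERK feedback genes, 5 rose and 1 fell, against 7 and 1 adjusted over the list alone (Etv4 0.72, Spry1 0.59, Dusp5 −0.64; group-alone camera adjusted p = 0.00147, adjusted p = 0.701 with an estimated correlation). Of 10 genes of the EGFR family and its ligands, 0 rose and 3 fell, against 1 and 6 adjusted over the list alone (Ereg −1.30, Erbb3 −0.59, Erbb2 −0.50; group-alone camera adjusted p = 0.0473, adjusted p = 0.752 with an estimated correlation). Of 13 FOXO targets, 0 rose and 3 fell, against 0 and 7 adjusted over the list alone (Insr −0.69, Cited2 −0.41; group-alone camera adjusted p = 0.0276, adjusted p = 0.701 with an estimated correlation). Of 20 glycolysis and hypoxia genes, 7 rose and 1 fell, against 9 and 1 adjusted over the list alone (Bnip3 0.49, Pgam1 0.48, Ndrg1 −0.68; group-alone camera adjusted p = 0.0213, adjusted p = 0.701 with an estimated correlation). Of 13 antimicrobial and NF-kB genes, 0 rose and 4 fell, against 0 and 5 adjusted over the list alone (Reg3g −0.69, Birc3 −0.66; group-alone camera adjusted p = 0.0400, adjusted p = 0.752 with an estimated correlation). The MHC class II list (4 tested) was called lower (group-alone camera adjusted p = 0.0213, adjusted p = 0.701 with an estimated correlation), though its only gene that fell, Cd74 (−2.64), was near the floor at 0.476 and 1.41 CPM in controls 1 and 2 and 0.0715 and 0.232 CPM in knockouts 1 and 2.

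The remaining lists were not called by camera in all cells. Members that rose and fell numbered 1 and 4, or 2 and 4 adjusted over the list alone, in the amino acid response (Trib3 −1.07, Chac1 −0.77), 3 and 1, or 5 and 2 adjusted over the list alone, in the unfolded protein response (Dnajb9 −0.49, Creld2 0.39), and 1 and 3, or 1 and 7 adjusted over the list alone, in the interferon response (Ifit3 −1.79, Irf7 −1.12, Cxcl10 1.03). They numbered 0 and 1, or 0 and 2 adjusted over the list alone, in the goblet list (Fcgbp −1.31), and 0 and 2, or 0 and 2 adjusted over the list alone, in the Paneth list (Defa17 −0.95, Pnliprp2 −0.41). The Notch response list had 1 and 0, or 2 and 0 adjusted over the list alone (Olfm4), the YAP and fetal-like list 0 and 1, or 0 and 1 adjusted over the list alone (Ereg) and the ribosomal list 0 and 2, or 0 and 0 adjusted over the list alone (Rpl27 −0.41, Rps27 −0.35). The sterol list was called lower by fry with the block (adjusted p = 0.0386). Fry with the group alone called 0 lists, as did camera with the block and an estimated correlation (smallest adjusted p = 0.583). No member passed over all genes in the enteroendocrine (Reg4 1.06, Gcg −0.19), tuft (Ltc4s −0.60) and secretory fate (Sox4 0.18, Xbp1 0.01) lists, nor adjusted over the list alone. Camera adjusted p for these 12 lists lay between 0.0598 and 0.50. Too few members of the other cell types were tested for camera. Egfl7, of the endothelial list, rose (0.79 ± 0.13, adjusted p = 0.0122), while Cd68 (−0.36), Lyz2 (−0.48), Vim (0.84) and Pdgfrb (−1.17) did not pass. Egfl7 stood at 11.8, 13.3 and 13.9 CPM in the epithelial clusters 1, 2 and 4. Cdh5, Kdr, Cldn5 and Emcn were at 0.0 CPM in every cluster, so its rise is no sign of endothelial cells.

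In stem-like cells camera called the p53 target and unfolded protein response lists higher and the ribosomal protein list lower in the knockout. With an estimated correlation it called 0 lists (smallest adjusted p = 0.615). Crypt base markers hardly set this class apart from cycling-like cluster 1 (Lgr5 128 against 123 CPM, Ascl2 90.9 against 101, Olfm4 3717 against 3010). Cluster 2 had less Lgr5 (45.7 CPM) and Olfm4 (650 CPM). Cell cycle genes differed more from cluster 1 (Mki67 63.3 against 339 CPM, Mcm6 152.5 against 103). The cycling-like class thus also holds cells with crypt base markers. Slc25a4 rose (1.02 ± 0.16, adjusted p = 3.32e-07), as did Agr2 (1.00 ± 0.12, adjusted p = 4.71e-14), a disulfide isomerase of mucus-producing cells, Gcnt3 (1.00), Bok (0.79) and Rnf168 (0.77). Edn1 (−1.18 ± 0.17, adjusted p = 4.99e-09), Rps27rt (−1.13, a near copy of Rps27 and so uncertain), S100g (−1.0), Tff3 (−0.95) and Hsd17b13 (−0.93) fell. Of 18 p53 targets, 3 rose and 0 fell, against 8 and 0 adjusted over the list alone (Plk2 1.20, Phlda3 1.10; group-alone camera adjusted p = 1.38e-04, adjusted p = 0.615 with an estimated correlation). Of 15 unfolded protein response genes, which serve folding in the secretory pathway, 3 rose and 0 fell, against 7 and 0 adjusted over the list alone (Hspa5 0.54, Hsp90b1 0.40; group-alone camera adjusted p = 6.56e-06, adjusted p = 0.615 with an estimated correlation). Of 78 ribosomal protein genes, 0 rose and 15 fell, against 0 and 24 adjusted over the list alone (Rpl36al −0.51, Rpl37a −0.41; group-alone camera adjusted p = 2.62e-21, adjusted p = 0.615 with an estimated correlation). Of 15 immediate early genes, 0 rose and 2 fell, against 0 and 5 adjusted over the list alone (Fosb −1.31, Atf3 −1.15; group-alone camera adjusted p = 1.79e-06, adjusted p = 0.615 with an estimated correlation). Camera also called ERK feedback (Phlda1 0.39) and glycolysis (Ldha 0.44) and S phase genes higher, and the amino acid response (Atf5 −0.64) lower, with adjusted p of 0.00751, 1.26e-04, 0.0197 and 7.21e-04, and adjusted p = 0.615, 0.788, 0.934 and 0.785 with an estimated correlation. In the crypt base stem cell list, 2 rose and 0 fell, against 2 and 1 adjusted over the list alone (Olfm4 0.55, Igfbp4 0.44; camera adjusted p = 0.989), with a median of −0.05 and a mean of 0.07. With the block camera also called the goblet and Paneth lists higher (adjusted p = 0.0217 and 0.0217) and the xenobiotic list lower (adjusted p = 0.0258), each with adjusted p = 0.860 with an estimated correlation. The goblet and Paneth lists nonetheless had negative medians (−0.41 and −0.39) and means, and in the Paneth list 0 rose and 2 fell, against 1 and 5 adjusted over the list alone.

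With the block, 46 genes rose and 99 fell of 9598 tested in stem-like cells, 136 of 145 with the same direction in both mice. Over the alternatives run with the block this count ranged from 2 (DESeq2) to 153 (DESeq2 size factors). With the group alone, edgeR called 3 higher and 4 lower, and DESeq2 called 0 (162 at unadjusted p under 0.05) without the block and 1 higher and 1 lower with it. The 7 were Slc25a4 (1.03 ± 0.19, adjusted p = 0.0469), Pthlh and the gene model Gm26917 among higher, and Cox17 (−0.84 ± 0.16, adjusted p = 0.0469), Rpl27 (−0.60 ± 0.12, adjusted p = 0.0469), Phpt1 and Rnaset2b among lower genes. Pthlh, Gm26917, Phpt1 and Rnaset2b lie outside the rule for naming genes and were chosen after their values were seen. Without control 1 the fold change of Slc25a4 was 0.53 (adjusted p = 0.670) and the adjusted p of Rpl27 was 0.129, and without knockout 1 the adjusted p of Cox17 was 0.125 and that of Rpl27 0.0557. Without knockout 2 Rpl27 was at 0.0838. Control 2 held only 16 stem-like cells. Leaving out each library moved the 7 calls to 35 without knockout 1, 14 without knockout 2, 38 without control 1 and 71 without control 2.

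In cycling-like cells camera called the p53 target and ERK feedback lists higher, and the Paneth, amino acid response and ribosomal protein lists lower, in the knockout. With an estimated correlation it called 0 lists (smallest adjusted p = 0.502). Slc25a4 (1.49 ± 0.13, adjusted p = 0.00282), Ccng1 (1.15 ± 0.09, adjusted p = 0.00188), Tnfrsf12a (1.01), Igfbp4 (0.95) and Cdkn1a (0.86 ± 0.13, adjusted p = 0.0252), the cell cycle inhibitor p21, rose. Tff3 (−1.54 ± 0.08, adjusted p = 3.34e-04), Defa24 (−1.44 ± 0.08, adjusted p = 3.34e-04), Rps27rt (−1.11), Defa30 (−1.05) and Nupr1 (−1.01) fell. Of 20 p53 targets, 9 rose and 0 fell, against 14 and 0 adjusted over the list alone (Phlda3 1.92 ± 0.11, adjusted p = 3.60e-04, Trp53inp1 1.72, Zmat3 1.27; group-alone camera adjusted p = 8.17e-09, adjusted p = 0.502 with an estimated correlation). Of 16 ERK feedback genes, 4 rose and 0 fell, against 10 and 1 adjusted over the list alone (Spry1 0.54, Ier3 0.53; group-alone camera adjusted p = 1.55e-07, adjusted p = 0.502 with an estimated correlation). Only part of this list, the Dusp, Spry and Spred genes, is known for limiting the signal of receptor tyrosine kinases. Its other members include Etv4, Ier3, Epha2, Myc and Ccnd1. This list was also called by fry with the group alone (adjusted p = 0.0179) and not with the block (adjusted p = 0.131). Of 10 Paneth cell genes, 0 rose and 5 fell, against 0 and 6 adjusted over the list alone (Ang4 −1.05; group-alone camera adjusted p = 2.46e-08, adjusted p = 0.502 with an estimated correlation). The Defa genes are near copies of each other and uncertain one by one. Of 78 ribosomal protein genes, 0 rose and 24 fell, against 0 and 50 adjusted over the list alone (Rpl27 −0.58, Rps27 −0.49; group-alone camera adjusted p = 8.00e-13, adjusted p = 0.559 with an estimated correlation).

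**Figure D3:**
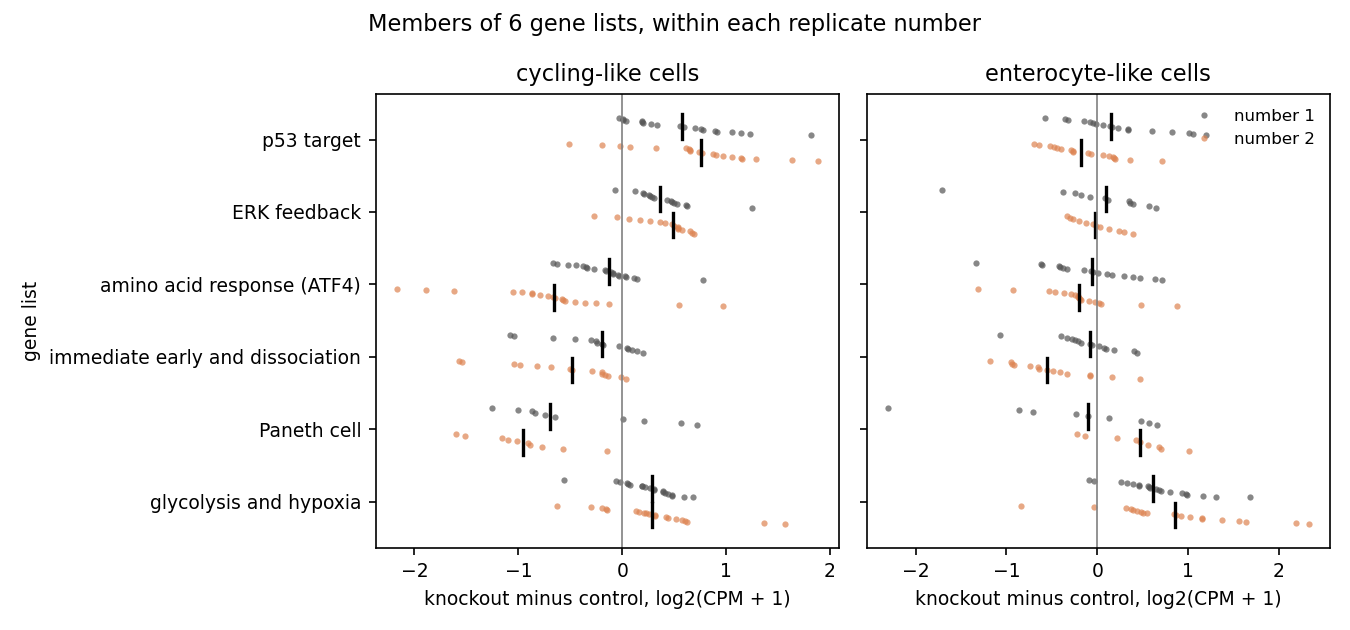
Points give the knockout minus control difference in log2(CPM + 1) of each member of 6 gene lists in cycling-like and enterocyte-like cells, grey for number 1 and orange for number 2, with black ticks at the medians. In cycling-like cells the medians of the p53 target list lie at 0.58 and 0.76.

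Other lists were also called in cycling-like cells. Of 20 amino acid response genes, 1 rose and 2 fell, against 1 and 11 adjusted over the list alone (Sesn2, also a p53 target, 0.97; group-alone camera adjusted p = 3.96e-09, adjusted p = 0.502 with an estimated correlation). Trib3 (−1.68), Chac1 (−1.61) and Atf5 (−1.14) passed adjusted over the list alone. Of 15 unfolded protein response genes, 4 rose and 0 fell, against 7 and 1 adjusted over the list alone (Pdia6 0.44, Hspa5 0.40; group-alone camera adjusted p = 3.68e-04, adjusted p = 0.502 with an estimated correlation). Of 20 glycolysis and hypoxia genes, 5 rose and 1 fell, against 13 and 1 adjusted over the list alone (Egln3 0.64, Ndrg1 −0.67; group-alone camera adjusted p = 2.95e-04, adjusted p = 0.502 with an estimated correlation). Of 15 immediate early genes, 0 rose and 4 fell, against 0 and 9 adjusted over the list alone (Hspa1b −1.53, Hspa1a −1.51; group-alone camera adjusted p = 3.30e-05, adjusted p = 0.502 with an estimated correlation). Of 6 goblet cell genes, 1 rose and 2 fell, against 1 and 4 adjusted over the list alone (Fcgbp −2.35, Agr2 0.75; group-alone camera adjusted p = 0.0298, adjusted p = 0.559 with an estimated correlation). Camera further called the S phase list higher (Tipin 0.35; group-alone camera adjusted p = 0.0267, adjusted p = 0.661 with an estimated correlation) and the antimicrobial list lower (Reg3b −1.50; group-alone camera adjusted p = 0.0366, adjusted p = 0.502 with an estimated correlation). With the block it also called the stem cell list higher and the xenobiotic list lower, both at an adjusted p of 0.0385, with adjusted p = 0.783 with an estimated correlation.

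With the block, 132 genes rose and 174 fell of 11466 tested in cycling-like cells, all 306 with the same direction in both mice. Over the alternatives run with the block this count ranged from 109 (DESeq2) to 1434 (doublets kept), and with no filter 615 rose and 605 fell. With the group alone, edgeR called 0 (830 at unadjusted p under 0.05) and DESeq2 16 higher and 30 lower. The smallest unadjusted p of that fit belonged to Creb3l1 (1.27 ± 0.13, adjusted p = 0.160), Gcnt3, Gimd1, Igfbp4 and Tmem173 among higher and Defa24, Mt4, Defa17, Defa30 and Moxd1 among lower genes. The count was 146 without control 1, 13 without control 2, 5 without knockout 1 and 0 without knockout 2. The cells of number 1 lay mostly in cluster 1 and those of number 2 in cluster 2. Both classes come from the same 4 libraries. Of the genes tested in both that passed with the block in stem-like and in cycling-like cells, 28 rose in both (0.6 if independent, of 46 and 123) and 61 fell in both (1.7, of 99 and 161).

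In enterocyte-like cells camera called the glycolysis and hypoxia list higher in the knockout. With an estimated correlation it called 0 lists (smallest adjusted p = 0.864). Hk1 (2.29 ± 0.33, adjusted p = 3.62e-04), Slc16a3 (1.72 ± 0.27, adjusted p = 0.0234), a lactate carrier, Egln3 (1.51 ± 0.16, adjusted p = 5.31e-06), Ankrd37 (2.18), Sprr2a3 (2.12), AA467197 (1.56) and the goblet gene Zg16 (4.2) rose. Zg16 was low in these cells, at 6.1 and 1.0 CPM in their clusters 3 and 13 against 1828.5 CPM in goblet-like cluster 5. Of 20 glycolysis and hypoxia genes, 10 rose and 0 fell, against 16 and 0 adjusted over the list alone (Hk2 1.29; group-alone camera adjusted p = 6.02e-16, adjusted p = 0.864 with an estimated correlation). Ctrb1, a protease precursor, had the largest fall among genes past the threshold with an average log2 CPM of at least 5 (−3.06 ± 0.24, adjusted p = 3.85e-08), with 128 and 67.4 CPM in controls 1 and 2 and 9.77 and 9.97 CPM in knockouts 1 and 2. Lct (−1.30 ± 0.26, adjusted p = 0.0160), G6pc (−1.26), Dnase1 (−1.25) and Coq8a (−1.14) also fell. Of 15 enterocyte genes 0 rose and 1 fell, against 0 and 1 adjusted over the list alone within this class, with a camera adjusted p of 0.852. With the block the median of that list was 0.05 and its mean −0.05. In the antimicrobial list, 2 rose and 1 fell, against 3 and 1 adjusted over the list alone (Duoxa2 2.13, Reg3g 0.72, Pigr −1.06). Camera called the ribosomal list lower (group-alone camera adjusted p = 2.33e-05, adjusted p = 0.864 with an estimated correlation) and the sterol list higher (group-alone camera adjusted p = 0.0378, adjusted p = 0.864 with an estimated correlation), with no single member past the threshold.

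With the block, 81 genes rose and 38 fell of 9015 tested in enterocyte-like cells, 116 of 119 with the same direction in both mice. Over the alternatives run with the block this count ranged from 15 (DESeq2) to 246 (at least 1000 genes). With the group alone, edgeR called 0 (238 at unadjusted p under 0.05) and DESeq2 4 higher and 1 lower. The smallest unadjusted p of that fit belonged to Zg16, Hk1, AA467197, Epop and Egln3 among higher and Ctrb1 (−3.23 ± 0.37, adjusted p = 0.186), Dnase1, Aida, Sardh and Timm10 among lower genes. The count was 45 without control 1, 2 without control 2, 2 without knockout 2 and 0 without knockout 1. With the block camera also called the immediate early list lower and the goblet list higher, with adjusted p of 3.81e-04 and 0.0347, and adjusted p = 0.884 and 0.884 with an estimated correlation. Cluster 13 held most enterocyte-like cells of control 1, and cluster 3 most of the other 3 libraries.

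In goblet-like cells many S phase and mitosis genes rose, and most Paneth genes fell, with the block. Tuba1a (ENSMUSG00000072235, chromosome 15, 98949837 to 98953703) was the only gene called in these cells with the group alone (1.56 ± 0.14, adjusted p = 0.0398), at 27.7 and 26.5 CPM in controls 1 and 2 and 87.1 and 79.9 CPM in knockouts 1 and 2. That call was lost with at least 1000 genes per barcode (log2 fold change 1.65, adjusted p = 0.185) and with doublets kept (1.40, adjusted p = 0.9998). Over its alternatives adjusted p ranged from 1.94e-14 to 0.9998. With the block, Slc25a4 (1.58), Reg4 (1.5 ± 0.10, adjusted p = 9.29e-49), Id4 (1.38) and Rcn1 (1.29) rose, while Aoc1 (−1.34), Defa22 (−1.15), Ccl6 (−1.15), Fosb (−1.14) and Fcgbp (−1.14 ± 0.10, adjusted p = 3.81e-26) fell. With 1 residual degree of freedom, such small adjusted p rest on spread pooled over genes and do not measure the spread between mice. By list, 26 of 42 S phase and 32 of 52 mitosis genes rose, and 7 of 10 Paneth and 11 of 15 immediate early genes fell, or 30, 40, 9 and 14 adjusted over the list alone. No test of lists was run in these cells. In all, 840 genes rose and 698 fell of 10370 with the block, 1522 of 1538 with the same direction in both mice, against 1 call by edgeR with the group alone (1235 at unadjusted p under 0.05) and 21 by DESeq2. Over the alternatives run with the block the count ranged from 136 (DESeq2) to 1540 (DESeq2 size factors), with 353 at 1000 genes or more, and with doublets kept the balance turned to 162 higher and 212 lower. That 1 call became 16 without knockout 1, 3 without knockout 2, 16 without control 1 and 6 without control 2. The makeup of the class ran the same way as these lists. Cluster 9, the more dividing part with lower Paneth genes (Mki67 278 against 57.9 CPM in cluster 5, Top2a 330 against 53.6 CPM, Defa24 17309 against 50361 CPM), held 29.95% and 15.1% of goblet-like cells in controls 1 and 2 and 45.2% and 35.99% in knockouts 1 and 2.

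Paneth-like cells, which secrete antimicrobial peptides at the crypt base, had 5 genes past the threshold with the block. With the block the defensin AY761184 (2.42 ± 0.18, adjusted p = 0.00335) rose, and Zg16 (−2.45 ± 0.17, adjusted p = 0.00335), Defa32 (−1.11), Defa20 (−0.98) and Defa17 (−0.97) fell, and these 5 were all calls among 6652 genes. Over the alternatives run with the block this count ranged from 3 (DESeq2 and limma) to 66 (at least 1000 genes, 45 higher and 21 lower), with 60 with no filter and 25 with equal cells. With the group alone, edgeR called 0 (465 at unadjusted p under 0.05) and DESeq2 1. The smallest unadjusted p of that fit belonged to Mcm7 (1.86 ± 0.35, adjusted p = 0.0863), Rgcc, Pgam1, Dut and Arhgdig among higher and Zg16, Fcgbp, Btg2, Trpm4 and Dusp1 among lower genes. Adjusted over the list alone, 9 of 25 S phase genes rose and 11 of 14 immediate early genes fell, and over all genes 0 of each. The count with the group alone was 113 without knockout 1, 23 without control 1, 8 without control 2 and 6 without knockout 2.

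The effect of the knockout was also compared between stem-like and enterocyte-like cells, a class of the crypt and a class of the villus. Of 10464 genes tested with edgeR, with the library as a block and no term for the mouse, the effect of 1 was higher and that of 2 lower in stem-like cells (385 at unadjusted p under 0.05). With the difference between the classes also allowed to differ by replicate number, added after the data were examined, the effect of 15 was higher and that of 27 lower, the 3 genes among them. Plaur, the urokinase receptor, differed by 3.29 ± 0.52 (adjusted p = 0.00516), with 3.52 and 4.72 CPM in control and 9.34 and 19.6 CPM in knockout stem-like cells against 61.9 and 28.8 and then 11.9 and 27.9 CPM in enterocyte-like cells. AA467197 differed by −3.23 ± 0.59 (adjusted p = 0.0161) and the gene model 2610528A11Rik by −2.38 ± 0.40 (adjusted p = 0.00753). Without control 1 the adjusted p of the 3 genes was 1.0, 0.117 and 1.0 in the same order, and without knockout 1 it was 0.00192, 0.419 and 0.0755. The count of 3 was 10 without knockout 1, 7 without control 1 and 12 without control 2.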

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

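Of the effects tested for a difference between stem-like and enterocyte-like cells, 3 genes passed the threshold in the planned edgeR interaction, and the values without single libraries were planned too, while the replicate block was added to it after the result was seen. Plaur (ENSMUSG00000046223, GRCm38 chromosome 7, 24462484 to 24475968) had an effect 3.29 higher on the log2 scale in stem-like than in enterocyte-like cells (SE 0.52, adjusted p = 0.00516), and without control 1 the value was 2.18 (adjusted p = 1.0). The gene model 2610528A11Rik (ENSMUSG00000096001, chromosome 14, 37102140 to 37114022) had a difference of −2.38 (SE 0.40, adjusted p = 0.00753), with 19.4, 3.15, 13.2 and 15.6 CPM in stem-like and 47.0, 4.29, 187 and 132 CPM in enterocyte-like cells of controls 1 and 2 and knockouts 1 and 2. Without knockout 1 it was −2.05 (adjusted p = 0.0755) and without control 1 −3.00 (adjusted p = 1.0). AA467197 (ENSMUSG00000033213, chromosome 2, 122636986 to 122641191) had a difference of −3.23 (SE 0.59, adjusted p = 0.0161), with 3.77, 7.86, 1.5 and 2.03 CPM in stem-like and 110, 104, 422 and 234 CPM in enterocyte-like cells. Without knockout 1 it was −2.42 (adjusted p = 0.419) and without control 1 −3.93 (adjusted p = 0.117). Over the other alternatives (DESeq2 size factors, no filter, the replicate block, without knockout 2, without control 2), all 3 genes stayed past the threshold, and adjusted p over all alternatives ranged from 2.20e-06 to 1.0 for Plaur, 1.49e-09 to 1.0 for 2610528A11Rik and 1.59e-05 to 0.419 for AA467197. Each difference rests in part on the 16 stem-like cells of control 2.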

How the results depend on the processing

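Of the settings in this part, the tests with the block in combination with another choice, the block in the interaction, limma with the block, the stem-like class at 10 cells per library and stem-like with cycling-like cells together were chosen after the data were examined, and all other settings before. Unless stated, the cause of a change was not tested. Counts are of genes called with the group alone in edgeR, which were 0 in all cells, cycling-like, enterocyte-like and Paneth-like cells, 1 in goblet-like, 7 in stem-like cells and 3 for the interaction.

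The replicate block gave 748 genes higher and 1213 lower in all cells, 145 in stem-like, 306 in cycling-like, 119 in enterocyte-like, 1538 in goblet-like and 5 in Paneth-like cells, and 933 (413 higher, 520 lower) in stem-like and cycling-like cells together, against 0 without it (905 at unadjusted p under 0.05). These counts with the block are not comparable between classes. The block removes the difference between mice that same-numbered libraries share and leaves 1 residual degree of freedom. It called 14 lists in all cells, 11 in stem-like, 13 in cycling-like and 5 in enterocyte-like cells, against 13, 8, 11 and 3. Among shares and gene lists it changed no call beyond those printed. In the interaction it gave 42 genes (15 higher, 27 lower). Of 365 log2 fold changes of named genes, 209 passed with the block and not without it, 3 had another sign without passing in either fit, and 0 lost a call. Many of these genes were named because they passed with the block, so the 209 restates that choice. The fit with the group alone had few calls to lose.

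With DESeq2 the counts were 19 higher and 98 lower in all cells, 0 in stem-like, 46 in cycling-like, 5 in enterocyte-like, 21 in goblet-like and 1 in Paneth-like cells. With no filter, which tests more genes of low count, they were 58 in stem-like, 294 in cycling-like, 21 in enterocyte-like, 311 in goblet-like and 31 in Paneth-like cells. With at least 1000 genes per barcode they were 1 in stem-like, 1 in cycling-like, 0 in goblet-like and 7 in Paneth-like cells. With doublets kept they were 3 in stem-like, 0 in goblet-like and 4 in Paneth-like cells. With equal cells per library they were 19 in stem-like and 2 in cycling-like cells. DESeq2 size factors moved no count past 1.5 times without the block.

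In the block fit, DESeq2 gave 274 higher and 625 lower in all cells, 2 in stem-like, 109 in cycling-like, 15 in enterocyte-like, 136 in goblet-like and 3 in Paneth-like cells. Limma with the block gave 3 in Paneth-like cells, and with class shares held fixed 53 higher and 38 lower in all cells. No filter with the block gave 1675 higher and 1830 lower in all cells, 1220 in cycling-like (615 higher, 605 lower), 218 in enterocyte-like and 60 in Paneth-like cells (35 higher, 25 lower). At least 1000 genes with the block gave 68 in stem-like, 639 in cycling-like, 246 in enterocyte-like, 353 in goblet-like and 66 in Paneth-like cells (45 higher, 21 lower). Doublets kept with the block gave 68 in stem-like, 1434 in cycling-like, 233 in enterocyte-like, 374 in goblet-like (162 higher, 212 lower, so the balance turned) and 10 in Paneth-like cells (7 higher, 3 lower). Equal cells with the block gave 1151 higher in all cells, 39 in stem-like, 644 in cycling-like, 23 in enterocyte-like, 698 in goblet-like and 25 in Paneth-like cells. The balance also turned in Paneth-like cells with no filter, at least 1000 genes and doublets kept (1 higher and 4 lower with the block alone), in cycling-like cells with no filter (132 and 174) and in all cells with shares held fixed. DESeq2 size factors with the block gave 517 in cycling-like cells. With at least 1000 genes or doublets kept, the cells were also clustered anew.

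Leaving out each library in turn, the counts ranged from 14 to 71 in stem-like, 0 to 146 in cycling-like, 0 to 45 in enterocyte-like, 3 to 16 in goblet-like and 6 to 113 in Paneth-like cells and from 4 to 12 for the interaction, and stayed at 0 in all cells (327 to 2036 at unadjusted p under 0.05). In stem-like cells Slc25a4 went from 1.03 to 0.55 (adjusted p = 0.737) with equal cells per library. Cox17 and Rpl27 lost their calls with at least 1000 genes (adjusted p = 0.109 and 0.0689) and with doublets kept (0.133 and 0.131), and DESeq2 called none of the 3. Without control 1, 3 genes passed with the opposite sign, Defa30 (2.27, lowest −0.93 without control 2) and Txnip (0.87, lowest −0.40 without control 2) in stem-like and Olfm4 (3.45, lowest −3.73 without knockout 1) in enterocyte-like cells. With a library left out, differences of unpaired mean shares ranged from −2.94 to 10.5 percentage points for stem-like cells (−1.25 without control 2, −2.94 without knockout 1), from −6.94 to 0.593 for goblet-like (0.593 without knockout 1), from −0.337 to 2.58 for enteroendocrine-like (−0.337 without control 2), from −24.3 to −4.21 for enterocyte-like and from 8.17 to 12.3 for cycling-like cells. With libraries thinned to one median depth the goblet-like difference was 0.018 and the Paneth-like difference −1.21. In 8 clusterings the enterocyte-like share was lower, and the stem-like and cycling-like shares higher, in the knockout of both mice. With libraries aligned by ComBat the cycling-like difference went from 10.2 to 3.62 points (from 13.5 to 1.88 in mouse 2) and the stem-like difference from 3.76 to 8.53 points.

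Camera with an estimated correlation called 0 lists in all cells and in stem-like, cycling-like and enterocyte-like cells. With the group alone, fry called 0 in all cells, stem-like and enterocyte-like cells and 1 in cycling-like cells. With the block it called 1 in all cells and 0 in each of these classes. In enterocyte-like cells camera called 5 lists with the block, 5 with the block and doublets kept, 5 with the block and at least 1000 genes, 6 with equal cells (6 with the block as well), 6 with no filter, and 2 to 8 with a library left out. Other limits on the mitochondrial share (10% or none) could not be tried, since the features hold no mitochondrially encoded gene, and the planned test of stem-like cells with at least 20 cells could not be run either. With a library left out the block fit has no residual degree of freedom and gives no test. The smallest tested samples were the 16 stem-like and 31 Paneth-like cells of control 2.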

Other observations

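The tests of capture loss, free RNA and tamoxifen below, the limits that decide the tests of cluster borders and depth, the values within clusters and the unthinned medians of Defa24 were chosen after the results were seen. The clusterings without called genes and at one median depth were planned, and the limits for the cluster mix and for a few secretory cells were set before. Glycolysis and hypoxia genes stood higher in the unnamed cluster led by Fabp6 as well, which lies outside the enterocyte-like class. All 20 members were higher in the knockout of both mice there, with medians of 0.98 and 1.00 on the log2 scale. In enterocyte-like cells the medians were 0.62 and 0.85, in goblet-like cells 0.52 and 0.46, and in enteroendocrine-like cells −0.01 and −0.28. p53 target genes had medians of 1.07 and 0.91 in the low-depth cluster led by Gm26917 and Lars2, with 19 and 18 of 20 members higher in mice 1 and 2. In enterocyte-like cells their medians were 0.16 and −0.09, in goblet-like cells 0.31 and 0.56, in Paneth-like cells 0.23 and 0.06 and in enteroendocrine-like cells 0.05 and 0.34. The cluster with Clu, Ly6d and Anxa1, low in Mki67 (10.9 CPM), had 0.36 and 0.66, with 9 cells in control 1. The medians thus do not simply follow cell division.

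Immediate early genes, which include Fos, Jun and the heat shock genes Hspa1a and Hspa1b, were lower in most cell types. Their medians in mice 1 and 2 were −0.20 and −0.49 in cycling-like, −0.05 and −0.63 in stem-like, −0.08 and −0.55 in enterocyte-like, −0.28 and −0.65 in goblet-like and −0.48 and −0.76 in Paneth-like cells. Enteroendocrine-like cells gave −0.38 and 0.81, with 11 cells in control 2. In goblet-like cells, whose levels of Paneth genes are far above those of cycling-like cells, the Paneth list had medians of −0.63 and −0.50. No test was run on these medians, and their members are not independent.

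p53 target genes were higher in knockout cycling-like cells, with 9 of 20 members past the threshold in the block fit and medians of 0.58 and 0.76. A different mix of clusters inside the class is argued against, since the list's median was at least 0.417 within each of clusters 1 and 2 in both mice (0.417 and 0.477, then 0.892 and 0.776). Exposure to tamoxifen or Cre activity, either of which may raise these genes through DNA damage, cannot be told apart from the loss of Cbl and Cblb, because 0 libraries have tamoxifen with intact genes. An effect of the deletion itself stays open on the same grounds.

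Enterocyte-like cells were fewer in the knockout of both mice. Cluster borders set by genes that the deletion changes are argued against, since without the genes called in any class test the difference was still −7.38 percentage points in the mouse with the smaller gap. A lower median depth of the whole library is argued against too, at −7.83 points with libraries thinned to one median depth. Depth within the enterocyte-like class was not made equal by this, so lower depth of these cells stays open. The class had 2359721 UMIs in 151 cells of control 1 and 920996 in 102 cells of knockout 1. In mouse 2 it had 4199542 UMIs in 227 control cells and 2508346 in 221 knockout cells. Loss of enterocytes in dissociation or capture could also lower the share and cannot be told apart from a change in the epithelium: the percentage of barcodes under 500 genes was lower in both knockouts, by −0.72 points at the smaller gap, but cells lost before capture leave no barcode. Less differentiation or a faster turnover in the knockout, and an effect of tamoxifen, stay open as untested.

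Paneth genes were lower in knockout cycling-like cells as a class, but by mouse and cluster they moved unevenly, with list medians of −0.71 and −0.02 in cluster 1 and 0.08 and −1.22 in cluster 2. Less free RNA from Paneth cells in the knockout libraries would lower the list alike in every class. The list did not fall alike, but the classes compared cannot decide the question. In enteroendocrine-like cells the list had medians of 0.69 and 1.41, at least 1.388 above cycling-like cells, and over the members the mean gap was 0.98 (SE 0.30) in mouse 1 and 1.93 (SE 0.65) in mouse 2, with 11 cells in control 2. Their cluster had Lyz1 at 1023 CPM, against 69.1 and 121 CPM in clusters 1 and 2, though Defa24 was alike (286.5 against 248 and 293 CPM). Its Paneth values therefore need not come from free RNA. The SE takes members as independent, and the Defa genes are near copies. In enterocyte-like cells the mean gap was 1.37 (SE 0.15) in mouse 2 but 0.26 (SE 0.31), within its spread, in mouse 1. In cluster 12, with 9 cells in control 1, it was 0.63 (SE 0.83) and 0.26 (SE 0.70), within its spread in both mice, so free RNA stays open. A few secretory cells inside the control class cannot be told apart from a change in all cells. Thinned to 5000 UMIs per cell, the median of Defa24 was 1 and 0 UMIs in controls 1 and 2 and 0 in both knockouts, too low to decide. Unthinned, at unequal depth, it went from 113 to 87.45 CPM in mouse 1 and from 62.9 to 91.2 CPM in mouse 2, with 0.529 as the higher of both log2 changes, while the means over cells went from 362 to 217 and from 413 to 188 CPM. A lower share of cells on the way to a secretory fate was not tested.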
